A study of Mus musculus with 6 samples.

How the data were processed

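Open chromatin was mapped with ATAC-seq (assay for transposase-accessible chromatin with sequencing, in which the Tn5 transposase inserts adapters into accessible DNA) in classical monocytes of mouse bone marrow. The cells were sorted as CD45+ CD11b+ Ly6C-high Ly6G-negative from C57BL/6J mice aged 11 to 15 weeks that carried E0771 tumours, a mouse mammary carcinoma line. Per the labels' protocols, each library came from 30000 to 75000 cells pooled from 2 mice, transposition ran at 37 °C for 30 min, and the first amplification took 5 PCR cycles, with further cycles set by real-time PCR. Marrow was taken 20 days after tumour implantation and 17 days after surgery. The surgery was either ligation of the left anterior descending coronary artery, which causes myocardial infarction (MI, 2 libraries, replicates 6 and 7), or a sham operation (4 libraries, replicates 3, 4, 8 and 9). Groups and replicate numbers were taken from the labels.

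The authors deposited 1 peak list per library, and these 6 lists were the starting point. The submitters' processing notes name Bowtie2, MACS2 and the mouse build mm10, with no versions, roles or settings. How duplicates, mitochondrial reads, the shift of reads to the Tn5 cut site and the peak threshold were handled is not given in the sources used here. Each deposited list has 5 columns, the position, a name and a score of the peak, without a header. The score is the authors' value for each peak, its scale is not given in the sources used here, and it served only to rank peaks within a list. Peaks were listed for each library on its own, so the lists can differ in length because of sequencing depth, the share of reads in open chromatin or the biology. Read numbers were not in the sources used here, the depth of each library is therefore unknown, and a missing peak shows only that the authors' threshold was not reached.

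Gene positions came from a RefSeq table of assembly GRCm38.p6, the assembly that mm10 names, with 21887 protein-coding genes. The table gives the span of each gene but neither its strand nor its exons. The planned promoter window around a transcription start was therefore replaced by a window of 1 kb around either annotated end of a protein-coding gene, and peaks are described as near a gene end, elsewhere in a gene body or outside genes. A peak near a gene end can lie at the 3′ end, can belong to a neighbouring gene, and internal promoters of genes with long predicted transcripts are missed. Coordinates are 1-based positions in mm10.

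Peaks of all 6 lists were merged into regions, and a library counted as having a peak in a region when at least 1 bp overlapped. The libraries were compared by the number of peaks, the genome covered, the share of peaks near a gene end, and the Jaccard index, which is the number of bases covered in both of 2 libraries divided by the number covered in either. Regions with a peak in 4 of 4 sham and 0 of 2 MI libraries were called sham-only, and regions with a peak in 2 of 2 MI and 0 of 4 sham libraries MI-only. Their number was ranked among the 15 ways of picking 2 of the 6 libraries. It was also divided by the number expected when the presence table was shuffled by random swaps that keep each library's and each region's total, with 200 draws after 20 burn-in rounds. The 95% range of the expected number is the central range over the draws.

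Group differences were tested with 2-sided exact permutation tests over the 15 choices of 2 of 6 libraries. Only for the number and ratio of sham-only and MI-only regions was p 1-sided, the share of choices with a value as high or higher. The smallest p this design can give is 0.0667, so no comparison could reach 0.05, and p-values measure only the spread between these pools. No list repeated another, the highest Jaccard index of a pair being 0.616. The 15 gene lists, with 275 members of which 273 were found in the table (Mx1 and Mx2 were not matched as protein-coding genes), were compared by the log2 odds of a peak near a gene end for list members against all other protein-coding genes of the same library, with 0.5 added to each count. The lists covered housekeeping genes, tissue-restricted genes outside blood, classical monocytes, neutrophils, T and NK lymphocytes, B lymphocytes, erythroid cells and megakaryocytes, stem and progenitor cells, antigen presentation and dendritic cells, interferon response, inflammatory cytokines and NF-kB, immunosuppressive myeloid genes, chemokine receptors and adhesion, glucocorticoid and adrenergic response, and the cell cycle. List genes among sham-only and MI-only regions (nearest gene end within 50 kb) were tested with 2-sided Fisher exact tests against regions with a peak in as many libraries. Benjamini-Hochberg adjustment was applied within each family.

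Genes were named by a rule fixed before the data were examined. It took list genes with a sham-only or MI-only region within 50 kb, the 10 regions of either kind with the highest mean within-list rank of score, those near a gene end first, and for each list the first 2 members in alphabetical order with a peak near a gene end in 6 of 6 libraries and the first 2 with a peak in 0 of 6. Some of the genes this rule takes are not reported here. The gene lists, tests and alternatives were also fixed before the data were examined. The alternatives left out each library in turn, kept the better-scoring 50% of each list, cut all lists to the 6179 best-scoring peaks, kept the 19 autosomes, required peaks to cover 50% of a region, used 500-bp windows, loosened the sham criterion by 1 library, used the overlap coefficient, widened the gene end window to 5 kb, narrowed the distance limit to 10 kb, and added 1 instead of 0.5. A further alternative, the 4 libraries MI 6, MI 7, sham 8 and sham 9 with lists as deposited or cut to 22998 peaks, was chosen after seeing the data.

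The counting of separated regions was tested on simulated presence tables with the library totals of the MI against sham comparison and 47770 regions. With no planted effect, 55 sham-only regions were counted where 66.15 were expected and 173 MI-only regions where 171.41 were expected. With 200 planted sham-only regions the count of 255 was set by the planting, and the step tested was the expected number, which stayed at 73.89 with a range from 59 to 92. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and bedtools 2.31.1 were used, the last to check overlaps, merged regions and nearest genes.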

Results

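Accessible chromatin was compared in bone marrow classical monocytes of tumour-bearing mice after myocardial infarction or sham surgery. Per its title, the study asks whether infarction reprograms innate immune cells and thereby accelerates breast cancer. The data comprise 6 peak lists, 2 from infarcted mice (MI 6 and MI 7) and 4 from sham-operated mice (sham 3, sham 4, sham 8 and sham 9), each from a pool of 2 mice. The lists held 25211 peaks in MI 6, 22998 in MI 7, 6179 in sham 3, 14370 in sham 4, 28556 in sham 8 and 41144 in sham 9. Sequencing depth is unknown, so a peak that is missing from a short list may have been open but under the authors' threshold.

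Housekeeping genes were open and genes of other tissues almost without peaks in all 6 libraries, where open means a peak within 1 kb of a gene end. A gene that was not open in this sense can still have peaks farther from its ends. Of 15 housekeeping genes, 13 were open in MI 6, MI 7, sham 8 and sham 9, 10 in sham 3 and 14 in sham 4. The housekeeping genes Gapdh, a glycolytic enzyme, and Eef1a1, a translation elongation factor, had a peak within 1 kb of a gene end in 6 of 6 libraries. So did the myeloid transcription factors Cebpb and Klf4 and the monocyte lysozyme gene Lyz2, the last chosen after its values were seen. Of 16 genes restricted to tissues outside blood, such as the liver gene Alb and the intestinal gene Cdx2, none had such a peak in MI 6, MI 7, sham 3, sham 4 or sham 8, and 1 had it in sham 9. Among the 18 classical monocyte genes, 9 had a peak near a gene end in MI 6, 8 in MI 7, 3 in sham 3, 7 in sham 4, 10 in sham 8 and 13 in sham 9. The chemokine receptor gene Ccr2, which monocytes need to leave the marrow, and the coagulation factor gene F13a1 had such a peak in 0 of 6 libraries.

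The share of peaks near a gene end was 40.8% in MI 6, 43.3% in MI 7, 57.0% in sham 3, 51.6% in sham 4, 38.1% in sham 8 and 30.6% in sham 9. The 95% Wilson intervals ran from 55.7% to 58.2% for sham 3, the shortest list, and from 30.2% to 31.1% for sham 9, the longest, and cover counting error only. The MI mean of 42.0% ± 1.80 (SD, n = 2) differed from the sham mean of 44.3% ± 12.1 (SD, n = 4) by less than the spread between sham libraries (exact permutation p = 0.867). Peak number averaged 24105 ± 1565 (SD, n = 2) after MI and 22562 ± 15457 (SD, n = 4) after sham surgery (exact permutation p = 0.933). The genome covered was 8.76 ± 0.78 Mb (SD, n = 2) and 8.11 ± 6.45 Mb (SD, n = 4), with an exact permutation p = 0.933. Genes with a peak near an end numbered 9880 ± 94.8 (SD, n = 2) and 8356 ± 3220 (SD, n = 4), with an exact permutation p = 0.733. Both MI libraries lay between sham 4 and sham 8 in peak number, covered genome and share near gene ends. The MI minus sham difference in peak number was 1542 with all libraries but -3919 without sham 3 and -1188.5 without sham 4, and the differences in covered genome and in share near gene ends also changed sign without either library.

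**Figure D1:**
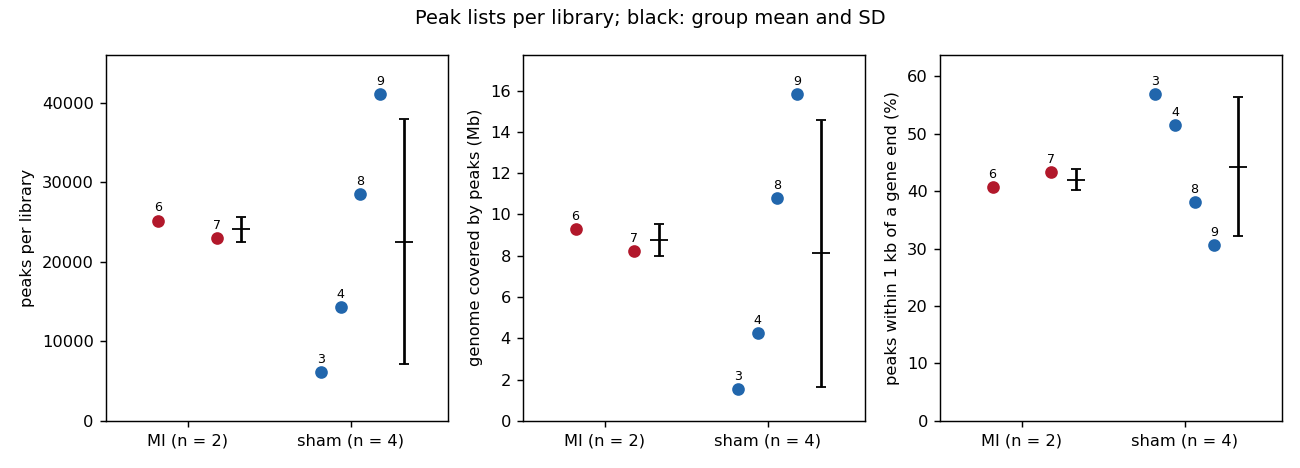
Number of peaks, genome covered in Mb and percent of peaks within 1 kb of a gene end, with 1 point per library, numbered by replicate, and the mean and SD of each group in black. The 2 MI libraries lie within the range of the 4 sham libraries in each panel, and the sham libraries range from 6179 to 41144 peaks.

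MI 6, MI 7, sham 8 and sham 9 shared more bases with each other, across the surgery groups too, than with sham 3 or sham 4. This split follows the replicate numbers, 3 and 4 against 6 to 9, and puts both MI libraries on one side, so that the MI minus sham values over all libraries also hold it; the labels name no batch. MI 6 and sham 8 shared the highest Jaccard index, 0.616, followed by MI 6 and MI 7 with 0.601, sham 8 and sham 9 with 0.557, and MI 7 and sham 8 with 0.554. The shortest list, sham 3, had indices from 0.0808 with sham 9 to 0.234 with sham 4, its own group. With all lists cut to 6179 peaks the separation stayed, with indices from 0.197 to 0.301 for sham 3, from 0.301 to 0.424 for sham 4 and from 0.580 to 0.668 among the other 4. The mean index was 0.302 within groups and 0.388 between groups, a difference of -0.0863 (exact permutation p = 0.267). Without sham 3 and sham 4, a comparison chosen after seeing the data, the difference was 0.0379, in the opposite direction.

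**Figure D2:**
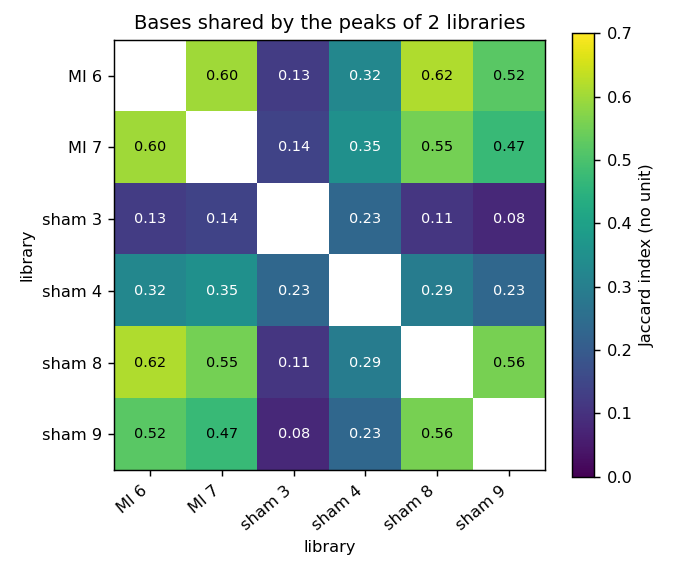
Jaccard index of covered bases for each pair of libraries, without unit, as colour and number. MI 6 and sham 8 form the most similar pair with 0.616, and sham 3 has no index above 0.234.

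The merged lists gave 47770 regions, of which 4240 had a peak in 6 of 6 libraries and 16620 in 1 library. Regions found in 6 libraries lay near a gene end in 76.2% of cases, regions found in 1 library in 12.4%. A peak near a gene end was present in every library for 3852 protein-coding genes and in none of the libraries for 10306.

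Few regions had a peak in every sham library and in no MI library. These 36 sham-only regions made up 0.484% of the 7441 regions with a peak in 4 libraries, where 6.67% would fall to each of the 15 possible patterns if all were alike. Of the 36, 4 lay within 1 kb of a gene end, 32 within 50 kb, and 18 overlapped a gene. The region at Nlrp1a, which encodes an inflammasome sensor, spanned chromosome 11 from 71144704 to 71145122 at an end of the gene. A region at Trpm2, a cation channel gene, spanned chromosome 10 from 77969752 to 77970072, also at a gene end. The other regions near gene ends were in Lcmt1 (chromosome 7, 123429910 to 123430183) and Lrrc49 (chromosome 9, 60687886 to 60688317). The best-ranked regions farther away lay inside Scnn1a (chromosome 6, 125333510 to 125333871), inside Hsf2, a heat shock transcription factor gene (chromosome 10, 57491994 to 57492401), and between genes nearest to Epb41l2 (chromosome 10, 25331719 to 25332091), Add3 (chromosome 19, 53273394 to 53273736) and Arhgef37 (chromosome 18, 61489603 to 61489896). Whether the regions inside genes are exonic or intronic is not given by the gene table used. None of the 36 was assigned to a member of the 15 gene lists.

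The count of 36 was not above the range expected from list lengths and region totals. Swaps that keep each library's and each region's total gave 29.8 sham-only regions with a 95% range from 20.0 to 41.0, a ratio of 1.21. Among the 15 ways to set 2 libraries apart, 36 ranked 5 (exact permutation p = 0.333) and its ratio ranked 2 (exact permutation p = 0.133), and 6651 regions were absent from sham 3 and sham 4 and present in the other 4 libraries. Leaving out a library moved the number to 352 without sham 3, 123 without sham 8, 66 without sham 4, 73 without MI 6 and 68 without MI 7. The ratio rose above its range without sham 8 (2.79), with the better-scoring 50% of each list (2.50) and with 500-bp windows (1.38). It was below 1 without MI 6 (0.328), without MI 7 (0.383), without sham 4 (0.713) and with all lists cut to 6179 peaks (0.302). In these equal lists 22 regions were sham-only, below the range from 59 to 90, and the ratio ranked 11 of 15.

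Regions with a peak in both MI libraries and in no sham library numbered 108, or 1.42% of the 7582 regions with a peak in 2 libraries. Of these, 13 lay within 1 kb of a gene end, 79 within 50 kb, and 59 overlapped a gene. They were weak peaks, with a median score percentile of 20.9 and a highest of 47.5 within their lists. For the sham-only regions these values were 42.7 and 67.0. Other regions with a peak in 2 libraries were not scored, so low scores may not be particular to the MI-only regions. List genes were Pgk1, a glycolytic enzyme of the housekeeping list, and Cybb, the phagocyte NADPH oxidase subunit gene of the immunosuppressive myeloid list. The Pgk1 region (chromosome X, 106187821 to 106188134) lay inside the gene 721 bp from an end, and a separate peak at an end of Pgk1 was present in 6 of 6 libraries. The Cybb region (chromosome X, 9452455 to 9452695) lay inside the gene 17203 bp from its nearer end. The best-ranked regions near gene ends were in Zfp772 (chromosome 7, 7209678 to 7210168), Ryr2, a calcium release channel gene (chromosome 13, 12106878 to 12107136), Pkn3 (chromosome 2, 30078093 to 30078343), Rbbp9 (chromosome 2, 144550716 to 144550982), Kif24 (chromosome 4, 41390196 to 41390477), Ttpa (chromosome 4, 20008143 to 20008414) and Sla2 (chromosome 2, 156874505 to 156874729). Further regions lay in Flrt3, which is within the span of Macrod2 (chromosome 2, 140671433 to 140671689), and 658 bp outside Ranbp9 (chromosome 13, 43481941 to 43482149).

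The MI-only count was lower than the swaps gave in the lists as deposited, and higher in lists of equal length. The expected number was 180.9 with a 95% range from 159 to 207, and the ratio of 0.60 ranked 8 among the 15 pairs (exact permutation p = 0.533). This p counts pairs with a ratio as high or higher and is no test for a low ratio. Other pairs also left their ranges, such as sham 3 with sham 4 at 26.3 and MI 7 with sham 8 at 0.37. The ratio of 0.60 is therefore not particular to the MI pair. By count the MI pair ranked 6 (exact permutation p = 0.4), and the pair sham 8 and sham 9 shared 3037 regions with no other library. Without sham 9, which has the most peaks, 1150 regions were MI-only, a ratio of 0.998 within its range, and with all lists cut to 6179 peaks 105 regions were MI-only, above the range from 68 to 100, with a ratio of 1.24 that ranked 2 of 15 (exact permutation p = 0.133) and a count that ranked 3 (exact permutation p = 0.2), beside 107 regions at a ratio of 1.24 for sham 8 with sham 9. Without 1 of the MI libraries, the regions found in the other alone numbered 817 without MI 6 and 907 without MI 7, and without sham 8 the MI-only number was 172.

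**Figure D3:**
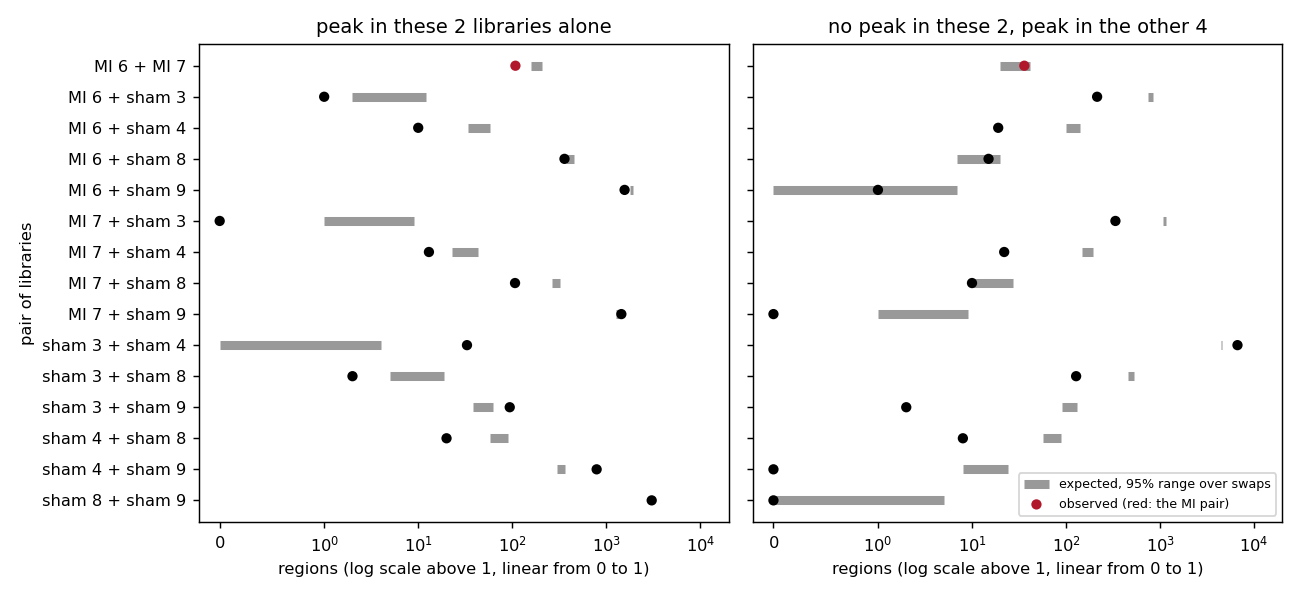
Number of regions with a peak in 2 libraries alone (left) and with a peak in all but those 2 (right), for each of the 15 pairs, on an axis that is logarithmic above 1. Points are observed numbers, and grey bars the 95% range expected when library and region totals are kept. The MI pair in red has 108 and 36 regions, against 6651 regions absent from sham 3 and sham 4.

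No gene of the 15 lists separated the groups at its ends. Of 273 list genes, 0 had a peak near a gene end in both MI libraries and no sham library, and 0 in all sham libraries and no MI library. A peak was present in all 6 libraries for 44 of them and in none for 82. Another 39 had a peak in MI 6, MI 7, sham 8 and sham 9 but not in sham 3 or sham 4, among them the monocyte gene Ly6c2, the neutrophil granule genes Camp, Ltf and Lcn2, and the erythroid gene Klf1, all chosen after their values were seen. Differences in log2 odds between MI and sham ranged from -0.90 for the tissue-restricted list to 1.25 for the erythroid list, with 8 lists above and 7 below 0. Both ends rest on values near the floor. The tissue-restricted list had 0 of 16 members open in every library but sham 9. The erythroid list had 0 of 16 open in sham 3 and 1 in sham 4. None of the 15 lists passed, with a smallest unadjusted exact permutation p = 0.133 and a smallest adjusted p = 0.90. An unadjusted p under 0.05, which the design cannot give, was found for 0 lists. The smallest p was that of the cell cycle list, which had 18 of 18 members open in MI 6, MI 7, sham 8 and sham 9. Each of the 15 lists changed the sign of its difference under at least 1 alternative, counting those chosen after seeing the data. Some of these changes came without a change in members. With the 4 longer lists the housekeeping difference was 0.24 although 13 of 15 members were open in each. The tissue-restricted and the T and NK lists changed sign only with these 4 lists at equal length, to 0.022. A change of sign alone therefore does not show an unstable list.

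The lists of immune genes were open in part in either group. Of 24 immunosuppressive myeloid genes, 12 had a peak near a gene end in MI 6, 10 in MI 7, 2 in sham 3, 9 in sham 4, 11 in sham 8 and 14 in sham 9. The lectin gene Lgals3 and the transcription factor gene Stat3 were open in 6 of 6 libraries. The arginase gene Arg1 and the scavenger receptor gene Cd163 had a peak near an end in 0 of 6. The list's log2 odds averaged 0.05 ± 0.30 (SD, n = 2) after MI and -0.14 ± 0.63 (SD, n = 4) after sham surgery (exact permutation p = 0.867). Of 23 interferon response genes, 17 were open in MI 6, 16 in MI 7, 3 in sham 3, 9 in sham 4, 16 in sham 8 and 19 in sham 9, with an exact permutation p = 0.467. The antiviral membrane protein gene Bst2 had a peak near an end in 6 of 6 libraries, and Gbp5 and Ifi44 in 0 of 6. Of 25 inflammatory cytokine and NF-kB genes, 15 were open in MI 6, 16 in MI 7, 6 in sham 3, 15 in sham 4, 14 in sham 8 and 20 in sham 9, with an exact permutation p = 0.867. The NF-kB subunit genes Rel and Relb were open in 6 of 6 libraries and the chemokine genes Ccl5 and Cxcl1 in 0 of 6.

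Of 20 antigen presentation and dendritic cell genes, 11 were open in MI 6, 12 in MI 7, 4 in sham 3, 7 in sham 4, 12 in sham 8 and 17 in sham 9 (exact permutation p = 0.933). Peaks at the peptide transporter gene Tap1 and the chemokine receptor gene Xcr1 were present in 6 of 6 libraries, but ends of Psmb8, Psmb9 and Fyco1 lie beside them. The class II transactivator gene Ciita and the integrin gene Itgax had no peak near an end in any of the 6 libraries. Among 17 chemokine receptor and adhesion genes, 10 were open in MI 6, 12 in MI 7, 2 in sham 3, 5 in sham 4, 9 in sham 8 and 12 in sham 9 (exact permutation p = 0.2), with Ccr1 and Cxcr4 open in 6 of 6 and Fpr2 in 0 of 6. Among 14 glucocorticoid and adrenergic response genes, 9 were open in MI 6, 10 in MI 7, 5 in sham 3, 7 in sham 4, 11 in sham 8 and 12 in sham 9 (exact permutation p = 0.6). The phosphatase gene Dusp1 was open in 6 of 6 libraries, and Adrb1 and Errfi1 in 0 of 6. Of 18 cell cycle genes, 18 were open in MI 6, MI 7, sham 8 and sham 9, 12 in sham 3 and 16 in sham 4 (exact permutation p = 0.133). The mitotic kinase gene Aurka and the cyclin gene Ccna2 were open in 6 of 6 libraries, beside ends of Cstf1 and Bbs7.

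Lists named for other cell types varied with the library, as the classical monocyte list did. These counts do not show whether cells that the sort should exclude were present in the pools. Of 17 neutrophil genes, 8 were open in MI 6, 9 in MI 7, 0 in sham 3, 3 in sham 4 and 11 in both sham 8 and sham 9, and Csf3r and Elane had no peak near an end in any of the 6 (exact permutation p = 0.733). The difference in log2 odds of the neutrophil list was 0.90 with the lists as deposited and 0.10 without sham 3. It was -0.32 with the better-scoring 50% of each list and -0.58 with the 4 longer lists, chosen after seeing the data. With all lists cut to 6179 peaks it was 1.47 (exact permutation p = 0.0667, the smallest possible). At that length sham 3 had 0 of 17 members open. Near this floor the 0.5 added to each count lets few open members set the value. Of 16 erythroid and megakaryocyte genes, 10 were open in MI 6, 7 in MI 7, 0 in sham 3, 1 in sham 4, 10 in sham 8 and 12 in sham 9 (exact permutation p = 0.533). Alas2 and Car1 had no peak near an end in the 6 libraries. Within 50 kb Alas2 had 2 peaks in MI 6, sham 8 and sham 9 and 1 in MI 7, while Car1 had 0 in each library. Of 14 stem and progenitor genes, 6 were open in MI 6, 5 in MI 7, 0 in sham 3, 2 in sham 4, 6 in sham 8 and 9 in sham 9, with Cdk6 and Erg at 0 of 6 (exact permutation p = 0.6). Of 16 B lymphocyte genes, 6 were open in MI 6, 5 in MI 7, 0 in sham 3, 1 in sham 4, 3 in sham 8 and 10 in sham 9, with Cd22 at 0 of 6 (exact permutation p = 0.467). Of 20 T and NK lymphocyte genes, 2 were open in MI 6 and sham 4, 3 in MI 7 and sham 8, 1 in sham 3 and 5 in sham 9 (exact permutation p = 0.2). An end of Cd3d had a peak in 6 of 6 libraries, and the ends of Bcl11b and Cd3e had none. The remaining lists gave p = 0.8 for housekeeping genes, p = 0.333 for tissue-restricted genes and p = 0.6 for classical monocyte genes, each by the same exact permutation test. Ywhaz of the housekeeping list had a peak near an end in 0 of 6 libraries. Within 50 kb, however, each of the 15 housekeeping genes had a peak in every library but sham 3, where 12 had one.

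**Figure D4:**
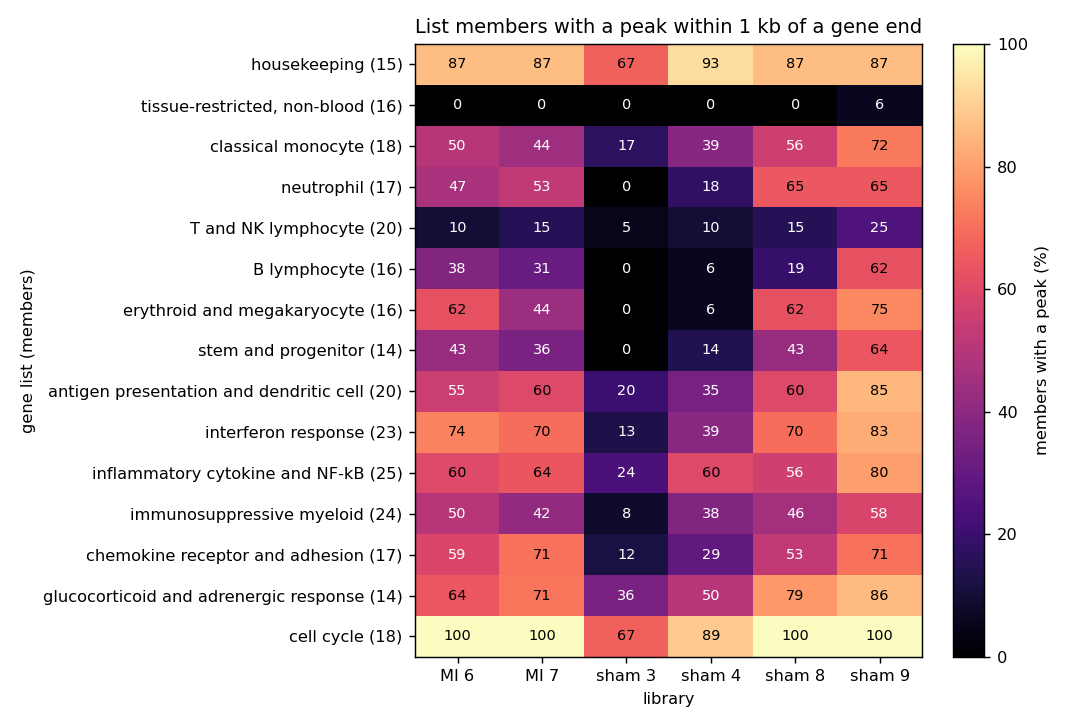
Percent of the members of each gene list, with the number of members in parentheses, that have a peak within 1 kb of a gene end in each library. Sham 3, with the fewest peaks, has the lowest percentage in each list except the tissue-restricted one, in which 5 libraries have 0.

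List genes were not concentrated among the separated regions either. Of 36 sham-only regions, 0 were assigned to a list gene, and of 108 MI-only regions 1 was assigned to the housekeeping list and 1 to the immunosuppressive myeloid list, where 19 of 7474 other regions with a peak in 2 libraries were. In the 30 Fisher exact tests over the 15 lists and both directions, 0 had an adjusted p under 0.05 and 0 an unadjusted p under 0.05, with a smallest unadjusted p = 0.0692 for Pgk1 in the housekeeping list. Regions are not independent replicates, so these tests describe the 6 libraries.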

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

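In the 35 sets of sham values examined for a sample far from the others, sham 3 stood apart in 2, and chance alone gives about 1 in 20. Sham 3 had 11.5 regions per 10000 near immunosuppressive myeloid genes, the lowest of the 4 sham libraries, with a gap to the next that was 0.881 of their range. It had the same value, 11.5 per 10000, near glucocorticoid and adrenergic response genes, with a gap of 0.933 of the range. Both values rest on 7 merged regions, and counted as peaks the gaps were 0.843 and 0.705 of the range, the second no longer apart from the others.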

How the results depend on the processing

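The comparison of the 4 longer lists (MI 6, MI 7, sham 8 and sham 9) was chosen after seeing the data; the other alternatives were planned. No paired analysis was possible because the groups share no replicate numbers. No setting made a gene list pass, or a list among separated regions, where unadjusted Fisher exact p values under 0.05 came up without sham 9 (0.0039, adjusted 0.1162), with 500-bp windows (0.0078), without sham 8 (0.0401), within 10 kb (0.0421) and without sham 3 (0.0483). No permutation p between the groups can reach 0.05, so those p values say nothing about stability. The MI minus sham difference in peak number ranged from -3919 to 7736 when 1 library was left out, being -3919 without sham 3, -1188.5 without sham 4 and -10745.5 with the 4 longer lists. For covered genome it was -1.54 Mb, -0.636 Mb and -4.56 Mb, and -1.73 Mb with the 4 longer lists at equal length, with up to 3.23 Mb without sham 9. For the share near gene ends it was -6.83 points without sham 9, 1.95 points without sham 3, 0.146 without sham 4, 6.70 with equal lists, 7.68 with the 4 longer lists and 1.57 at their equal length. Within minus between similarity was 0.0379 with the 4 longer lists and 0.0188 at equal length. Leaving out 1 library gave 37 to 352 sham-only and 108 to 1150 MI-only regions. The better-scoring 50% of each list gave 17 and 19, 500-bp windows 55 and 204, equal lists 22 sham-only, the looser sham criterion 471 and 1188, the 4 longer lists 3420 sham-only, and these at equal length 926 and 770. The sham-only ratio was 0.328 without MI 6, 0.383 without MI 7, 0.713 without sham 4, up to 2.79 without sham 8, 0.302 with equal lists, 2.50 with the better-scoring 50%, 1.38 with 500-bp windows, 1.06 with the 4 longer lists at equal length, 0.919 when peaks had to cover 50% of a region and 0.965 with the 4 longer lists. The MI-only ratio was 0.998 without sham 9, 0.984 with the 4 longer lists, 1.24 with equal lists and 1.11 with the 4 longer lists at equal length. Shorter lists and fewer libraries change these numbers by construction; otherwise the cause was not tested. Unknown depth limits every absence of a peak.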

Other observations

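The genes with the most regions shared by at least 4 libraries, each the nearest gene within 50 kb, included Chd7 and Litaf with 10 regions each. Chd7 encodes a chromatin remodeller. Irf2, an interferon regulatory transcription factor gene, Emb, Notch2 and Zfp608 had 9 each, and the transforming growth factor signalling gene Smad3 had 8. Acod1, which encodes the enzyme that makes itaconate in activated macrophages, had 7 regions, all 7 with a peak in MI 6, MI 7, sham 8 and sham 9, 4 in sham 4 and 0 in sham 3. The chemokine receptor gene Ccr1 had 15 regions in at least 1 library, 10 of them in MI 6, 9 in MI 7, 1 in sham 3, 5 in sham 4, 12 in sham 8 and 14 in sham 9.

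Peaks assigned to the nearest gene within 50 kb reached most monocyte genes in every library but sham 3. Of 18 classical monocyte genes, 17 had such a peak in MI 6, MI 7 and sham 8, 18 in sham 9, 13 in sham 4 and 6 in sham 3. Of all protein-coding genes, 54.1% had one in MI 6, 52.6% in MI 7, 21.9% in sham 3, 40.9% in sham 4, 55.9% in sham 8 and 63.3% in sham 9. Per 10000 peaks, 16.3 in MI 6 and 17.4 in MI 7 lay near the monocyte genes, against 11.3 in sham 3, 16.0 in sham 4, 16.8 in sham 8 and 18.7 in sham 9.

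All tests in the following paragraphs were chosen after the results were seen.

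Peaks near erythroid and megakaryocyte genes were unevenly spread. Within 50 kb, 13 of 16 genes had a peak in MI 6 and sham 8, 9 in MI 7, 14 in sham 9, 2 in sham 4 and 0 in sham 3, and the band 3 gene Slc4a1 had 4 peaks in MI 6 and MI 7, 5 in sham 8 and sham 9 and 0 in sham 3 and sham 4. Myocardial infarction as the only cause of this unevenness is argued against by the sham libraries themselves. With lists cut to 14370 peaks sham 8 had 11 members with a peak and sham 9 had 8. These 2 sham libraries thus reached or exceeded the lower MI library with 4. The counts in the full lists were known when the pattern was picked, so this is no separate test. A contribution of infarction was not excluded. Shorter peak lists cannot be told apart from a real difference, since in these equal lists sham 4 had 2 members with a peak where the other 4 had from 4 to 11, with an SD of 2.94, while 1.79% of random lists in sham 4 and 1.86% in sham 3 had as few members with a peak. A hypothesis is that erythroid or megakaryocyte cells in the sorted pools, which the CD45, CD11b and Ly6C gate should remove, may add such peaks, but no value decides it. Of 10000 random lists of 16 genes, 97.7% had fewer members with a peak in MI 6, 96.9% in sham 8 and 96.7% in sham 9 but 51.8% in MI 7, where the globin gene Hbb-bt had 1 peak as in MI 6, against 2 in sham 8 and sham 9, and open erythroid genes in the monocytes themselves were not tested.

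Among the 4 longer lists cut to 22998 peaks, regions found in 2 libraries alone exceeded the expected number most for MI 6 with sham 8 (945 regions, 1.20 times) and MI 7 with sham 9 (917, 1.19 times), and fell short of it for the other cross pairs, MI 7 with sham 8 (417, 0.57 times) and MI 6 with sham 9 (713, 0.86 times). The pairs within groups also lay above their ranges, with 1.11 for MI 6 with MI 7 and 1.06 for sham 8 with sham 9. In the lists as deposited the ratios were 1.13 for MI 6 with sham 8 and 1.31 for MI 7 with sham 9. At equal length both stayed above their ranges, the lower ratio being 1.19. The cut keeps all of MI 7 but only the best-scoring peaks of the others, so it cannot decide on list length or depth. These 2 pairs were picked for their ratios. They are the 2 sides of 1 split of the 4 lists and count as 1 observation. Myocardial infarction as the cause of this excess is argued against only by the make-up of the pairs, since each holds a library of either group. The lower number of 917, above its range from 731 to 814, was known when the pairs were picked and is no separate test. A separate effect of infarction was not excluded, the mean Jaccard index being higher within than between groups by 0.0188 at equal length. The MI 7 and sham 9 regions were found in sham 4 in 19.6% of cases and in sham 3 in 3.27%. For the MI 6 and sham 8 regions the shares were 4.34% and 0.529% (Fisher exact adjusted p = 2.6e-25 and 8.6e-06). Regions are not independent replicates, so these p values cover counting error within these lists and not the spread between pools. The shares could come from a difference between libraries that sham 3 and sham 4 also carry and that the labels do not name. Its source was not tested. Of the 15 gene lists, 0 passed a Fisher exact test between the 2 sets of regions (smallest unadjusted p = 0.119, smallest adjusted p = 1.0).

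Peaks near inflammatory cytokine and NF-kB genes were most frequent in sham 4, with 33.4 per 10000 peaks against 14.6 in sham 3, 20.0 in sham 8, 22.8 in sham 9, 21.8 in MI 6 and 23.5 in MI 7. In equal lists sham 4 had 48 such peaks and the other 4 libraries from 25 to 31, with an SD of 3.46. These lists cannot decide on list length, since the cut keeps all of sham 4 but only the best-scoring peaks of the others. Near immunosuppressive myeloid genes sham 4 had 21.6 per 10000 peaks, and the other 4 from 20.0 to 22.2. In equal lists sham 4 nevertheless had 31 such peaks against 21 to 23. The excess does not rest on 1 gene, since 43 peaks were left without the monocyte chemokine gene Ccl2, which had 5 in sham 4 and 0 in the other 4 equal lists; Cd83 and Tnfaip3, targets of NF-kB, had 5 each in sham 4 and at most 2 in each of those lists, and of the 25 genes 11 lay above the highest other list in sham 4, 7 were equal and 7, such as Tnf and Cxcl2, lay below it. Sham 3, too short for this comparison, and the full sham 9 list did have a peak near an end of Ccl2. Counting error stays open, since sham 4 against the highest of the others gave a Fisher exact p = 0.071, before any correction for the 15 lists, and no biological explanation was tested.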
